A study of Mus musculus with 8 samples.

How the data were processed

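Liver RNA was sequenced from 8 C57BL/6 mice. According to the design text 4 of these mice were HuR wild type (WT) and 4 were HuR knockout (KO), with 1 library per mouse, so the replicates are separate animals. HuR is an RNA-binding protein encoded by Elavl1. Per the labels' protocols, livers were stored frozen, total RNA was isolated with a Nucleospin RNA II kit, and mRNA was enriched and converted to strand-specific libraries with the NEBNext Ultra Directional kit. The exons deleted, the cells in which they were deleted, the age of the mice and the day of collection were not given in the sources used here. The sample titles hold an animal number, and these numbers form a pair of series, numbers from 98 to 100 and numbers of 4 digits. The first series holds WT replicate 3 and KO replicates 3 and 4, and the 4-digit series holds the other 5 libraries. What separates the series is not stated.

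The deposited table holds raw read counts per gene for each library. Per the submitters' processing notes, reads were handled with bcl2fastq 2.19.1, aligned with GSNAP and counted with featureCounts 1.5.1, on genome build mm10 (GRCm38). Per the file headers, the authors counted reads against the Ensembl 81 gene annotation with strand setting 2 (reversely stranded), which matches a directional kit of this type, and a minimum mapping quality of 1. The command recorded in the file headers has no option for reads that map to several places or overlap several genes. Such reads are therefore left out, and the levels of genes with near-identical copies, such as Mup3, Sult3a2, the haemoglobin genes and the Saa genes, are uncertain. The table has 45706 Ensembl gene rows and 92 rows for ERCC spike-in sequences, which held 0 counts in all libraries and were not used. Of the gene identifiers, 45143 matched a symbol. Coordinates are those of the deposited table, on mm10.

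Total gene counts per library ranged from 18649618 to 31249286. No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom over all pairs being 16.7, so each was kept as a replicate. Xist was counted 16005 to 33496 times per library and each of 4 Y-linked genes at most 1 time, which is the pattern of female mice. All libraries thus came from 1 sex, and a sex covariate was not run. Same-numbered replicates of the groups were not treated as pairs.

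Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, libraries were scaled by TMM (trimmed mean of M values), and groups were compared by edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) with Benjamini-Hochberg adjustment over the 14645 genes tested. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change was derived from the quasi-likelihood F statistic. Levels are counts-per-million (CPM) values scaled by TMM, and log2 CPM used a prior count of 2. Directions are always the libraries labelled KO against the libraries labelled WT. Single values per library were compared by exact two-sided permutation tests, for which 4 against 4 libraries give a smallest p of 0.0286.

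Before the data were examined, 34 gene lists were fixed, of which 33 were tested and the list of sex chromosome genes served as a check. Lists were tested with camera of limma 3.58.1, which asks whether a list's genes moved further in one direction than other genes, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list and fry were alternatives. Members called were counted from the edgeR test over all genes and, separately, adjusted over the list alone. The genes to be named were also fixed by rule: Elavl1, then the 10 highest and 10 lowest fold changes and the 3 smallest p in each direction among called genes with a mean log2 CPM above 0 and no overlap between groups, then up to 4 called members of each list in order of p, or where none was called up to 2 members with the smallest p. Predicted gene models and antigen receptor segments were counted but not named, and a few genes that the rule selects are not reported here. Other genes named in the closing section were chosen after their values were seen.

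The edgeR step was tested on simulated counts for the comparison of KO against WT, drawn for 14645 genes from the means and library sizes of the data. It recovered 24 of 50 genes changed 1.5-fold, 34 of 50 changed 2-fold, 47 of 50 changed 3-fold and 48 of 50 changed 4-fold, and called 7 of 14445 unchanged genes. A change of 1.5-fold was thus missed about as often as it was found. The camera step called the 1 shifted list and 0 of 20 unshifted lists. Each gene was drawn independently, with a spread set by its level. The simulation therefore cannot show how often camera calls lists of correlated genes. In the data the estimated correlation was as high as 0.614, for oxidative phosphorylation. Alternatives were RLE and upper quartile scaling, no low-count filter and a stricter filter (at least 1 CPM in at least 4 libraries), the replicate number as a block, the number series as a covariate, DESeq2 1.42.0, limma-voom with quality weights, edgeR's glmTreat against a fold of 1.5, and leaving out each library in turn. Restricting the comparison to the animals with 4-digit numbers was chosen after the data had been seen.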

Results

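Gene expression was measured by RNA-seq in the livers of 4 mice labelled HuR WT and 4 mice labelled HuR KO, to ask how the liver transcriptome differs between the genotypes. Total gene counts ranged from 18649618 to 31249286 per library, and 14645 genes were tested. The first principal component, which held 34.4% of the variance, separated the groups, from −37.1 to −2.33 in the libraries labelled WT and from 14.6 to 34.7 in those labelled KO. WT replicate 3 lay at −2.33, and the other WT libraries lay at −27.2 or below. Over all tested genes WT replicate 3 lay about as far from the other WT libraries as from the KO libraries, at a mean root-mean-square log2 CPM difference of 0.597 and 0.586. The library nearest to it was KO replicate 4. Albumin took 10.2% ± 0.63 of counts in the libraries labelled WT and 9.72% ± 0.76 in those labelled KO (SD, n = 4 each, exact permutation p = 0.371). Transcripts of the mitochondrial chromosome took 5.88% ± 0.55 and 7.09% ± 0.44, with no overlap between the groups (exact permutation p = 0.0286, the smallest this test allows). Of these, mt-Co1 was at 15687 and 16682 CPM in the libraries labelled WT and KO. By contrast, mt-Co2 was at 7.08 and 8.43 CPM and mt-Co3 at 5.89 and 7.59 CPM. The share thus rests on part of the chromosome's genes.

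Elavl1, the gene encoding HuR (ENSMUSG00000040028, mm10 chromosome 8, 4284782 to 4325100, minus strand, protein-coding), was not lower in the libraries labelled KO. It was counted at 42.0 ± 6.41 CPM in the libraries labelled WT and at 50.02 ± 4.33 CPM in those labelled KO (SD, n = 4 each). Per library the values were 32.7, 45.7, 42.9 and 46.6 CPM in WT replicates 1 to 4 and 49.4, 56.0, 49.1 and 45.6 CPM in KO replicates 1 to 4. The log2 fold change was 0.25 (SE 0.11, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.258), with an unadjusted 95% interval from 1.01-fold to 1.41-fold, and the exact permutation p of the log2 CPM was 0.0857. The log2 difference was 0.34 among the animals with 4-digit numbers and 0.14 among those numbered 98 to 100, where the WT group is a single library. The gene count sums reads over 6 exon blocks of 6030 bp in all, the longest of which holds 85.3% of that length, and the labels do not say which part was deleted, so the gene count cannot check the genotype labels. All directions given here are therefore directions between the libraries labelled KO and the libraries labelled WT.

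Genes of bile duct cells, extracellular matrix and fetal liver were higher in the libraries labelled KO, and Hpx and Slco1a1 of hepatocytes were lower. Spp1, which encodes the secreted protein osteopontin and is expressed by bile duct cells, rose 3.84-fold, from 43.1 ± 9.48 to 166 ± 43.0 CPM (SD, n = 4 each). H19, an imprinted non-coding RNA abundant in fetal liver, rose 11.1-fold, from 3.79 ± 1.59 to 42.2 ± 14.5 CPM. Hpx, which encodes the haem-binding plasma protein hemopexin, fell 4.89-fold, from 3482 ± 696 to 712 ± 141 CPM, and Slco1a1, an organic anion uptake transporter of hepatocytes, fell 42.2-fold, from 13.1 ± 5.39 to 0.300 ± 0.287 CPM. The size of that fall is uncertain because the levels labelled KO were near 0. The log2 fold change was −5.40 over all libraries, −6.585 by limma-voom, −6.16 without KO replicate 2 and −4.80 among the animals with 4-digit numbers. For these 4 genes every library labelled KO lay beyond every library labelled WT, with adjusted p from 1.85e-05 for Hpx to 0.00352 for H19 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

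**Figure D1:**
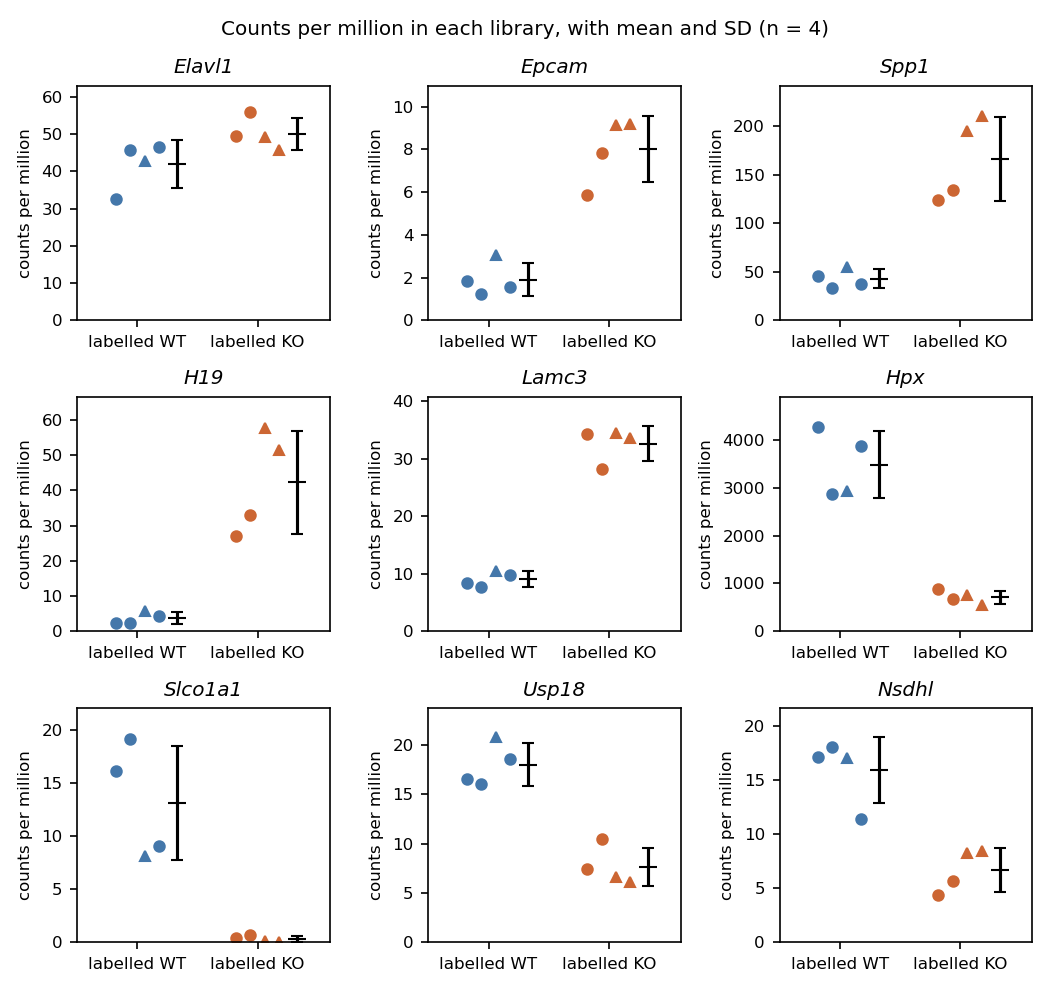
Counts-per-million values (CPM, vertical axes, linear, starting at 0) of 9 genes in each library labelled WT (blue) and KO (orange). Circles are animals with 4-digit numbers, triangles those numbered 98 to 100, and the black bars give the mean and SD (n = 4). Elavl1 overlaps between the groups, at 42.0 ± 6.41 and 50.02 ± 4.33 CPM, and the other 8 genes do not overlap.

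In all, 340 genes rose and 201 fell in the libraries labelled KO at an edgeR adjusted p under 0.05, 190 and 41 of them by at least 2-fold. Among called genes with a mean log2 CPM above 0 and no overlap between the groups, the largest rises besides that of H19 were those of Sftpd, an innate immune lectin (log2 fold change 4.43, SE 0.41, from 0.243 to 5.61 CPM), the matrix metalloproteinase gene Mmp7 (3.88, SE 0.34, from 0.521 to 7.62 CPM), the zinc transporter gene Slc39a5 (3.08, SE 0.47) and the tetraspanin gene Tspan8 (3.03, SE 0.30). They were followed by Myo5c, Spint1, Muc1, Ankrd1 and Gpc3 with log2 fold changes of 2.84, 2.58, 2.55, 2.48 and 2.43, the last 1.65 among the animals with 4-digit numbers. Lamc3, a laminin chain of basement membranes, had the smallest p among the genes that rose (log2 fold change 1.84, SE 0.13, from 9.09 ± 1.32 to 32.6 ± 2.98 CPM, edgeR adjusted p = 7.75e-06). After Slco1a1 and Hpx, the largest falls among such genes were those of Sult5a1 at −2.06, Col20a1 at −1.63, Sult3a2 at −1.63, Ifi27l2b at −1.48, Exd1 at −1.41, Med12l at −1.38, Dnase1l2 at −1.29 and Cenpq at −1.26. Dlst, which encodes a subunit of the 2-oxoglutarate dehydrogenase complex, fell from 243 ± 15.5 to 126 ± 8.21 CPM, and Zpr1 fell from 97.0 ± 17.4 to 41.6 ± 3.73 CPM (edgeR adjusted p = 0.000135 and 0.000164). The counts depended on single libraries: without WT replicate 3 they were 710 and 534, and without WT replicate 2, where they were lowest, 151 and 71.

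**Figure D2:**
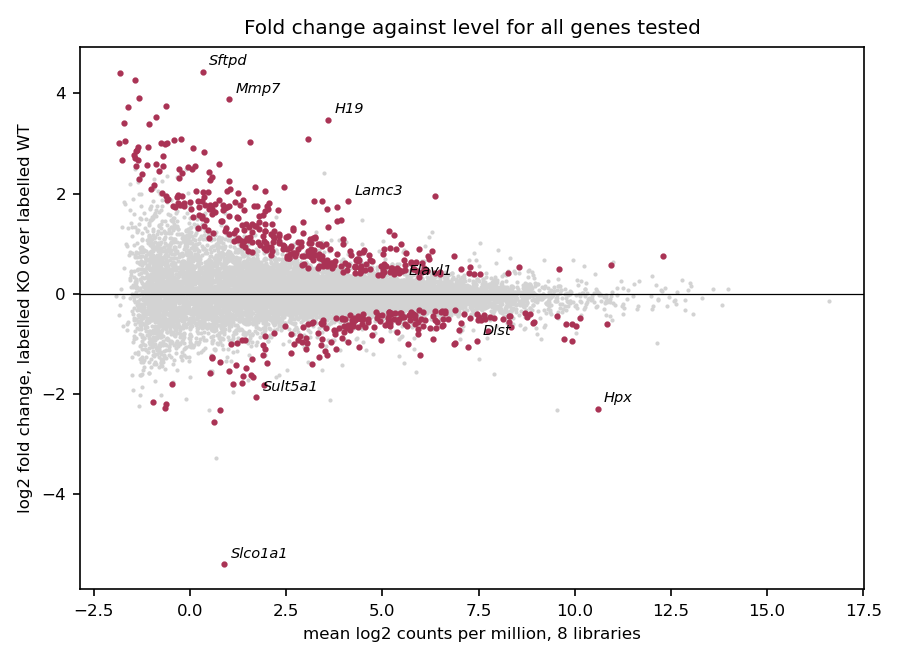
Log2 fold change (vertical axis, libraries labelled KO over libraries labelled WT) against mean log2 CPM over the 8 libraries (horizontal axis) for the 14645 genes tested. Red points are the 541 called genes and grey points all others. Elavl1 lies at 0.25 and is not called, Sftpd at 4.43 and Slco1a1 at −5.40.

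Camera called 10 of the 33 gene lists at its preset correlation, 4 up and 6 down, and 4 of them with an estimated correlation. Of 14 measured markers of bile duct cells, 11 rose, 0 fell and 3 were not called, with a median log2 fold change of 1.90 (13 rose adjusted over the list alone). Epcam, an adhesion molecule of biliary epithelium, rose from 1.91 ± 0.79 to 8.01 ± 1.54 CPM, Krt7, a keratin of bile duct cells, from 0.627 ± 0.154 to 3.04 ± 0.911 CPM, and Cd24a from 2.72 ± 0.201 to 8.76 ± 2.45 CPM (SD, n = 4 each, edgeR adjusted p = 0.000902, 0.00194 and 0.000902). The list was called by camera, with adjusted p = 0.0372 with an estimated correlation. Its median was 1.34 among the animals with 4-digit numbers and 1.73 among those numbered 98 to 100. Fewer members rose without WT replicate 1, WT replicate 2 or KO replicate 4, with 7 each, and 11 rose without WT replicate 3.

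Of 11 measured genes of fetal liver and liver tumours, 7 rose and 4 were not called, with a median of 1.68 (9 rose adjusted over the list alone; camera adjusted p = 0.0424 with an estimated correlation; 2 of the 7, Cd24a and Prom1, also stand on the bile duct list). Sox4, a transcription factor of progenitor cells, rose from 5.07 ± 0.609 to 11.7 ± 2.27 CPM, and Bex1 from 0.0509 ± 0.0357 to 1.06 ± 0.279 CPM (edgeR adjusted p = 0.00157 and 0.00198). Of 28 genes of the extracellular matrix and fibrosis, 11 rose and 17 were not called, with a median of 0.56 (23 rose adjusted over the list alone; camera adjusted p = 0.0424 with an estimated correlation). Timp2, an inhibitor of matrix metalloproteinases, rose with a log2 fold change of 0.68. Col4a1, a collagen chain of basement membranes, rose with 0.62, Bgn with 0.54 and Sparc with 0.49. The matrix count was 6 without WT replicate 2 or KO replicate 4, 7 without KO replicate 3 and 12 without WT replicate 3. Of 16 stellate cell markers 2 rose, Cygb 1.85-fold and Hgf 1.38-fold (4 adjusted over the list alone, median 0.22), and camera called the list only at its preset correlation (adjusted p = 0.187 with an estimated correlation). The stellate count was 3 without WT replicate 3 and 1 without WT replicate 1, 2 or 4 or KO replicate 1, 2 or 4. The medians of these lists were 1.07, 0.42 and 0.17 among the animals with 4-digit numbers and 1.83, 0.57 and 0.27 among those numbered 98 to 100.

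The mean log2 level of the 20 endothelial markers was 0.08 higher in the libraries labelled KO (SE 0.03, exact permutation p = 0.0286). It was 1.57 higher for the bile duct markers (SE 0.17, exact permutation p = 0.0286). That of the macrophage markers was 0.23 higher (SE 0.13, exact permutation p = 0.143), and that of the lymphocyte markers was lower, at −0.23 (SE 0.24, exact permutation p = 0.429). Camera over the 8 libraries did not call the endothelial, macrophage or lymphocyte list, and edgeR called none of their members. The lymphocyte median was −0.18, and it turned to 0.09 without WT replicate 1. The macrophage median was 0.09, with −0.07 among the animals with 4-digit numbers. Among the animals with 4-digit numbers alone camera called the lymphocyte list at its preset correlation, with a median of −0.26 (adjusted p = 0.00153), and its median was 0.01 among those numbered 98 to 100. Rspo3 and Pecam1 of the endothelial list had log2 fold changes of 0.42 and 0.23, and Cx3cr1 and Itgam of the macrophage list 1.26 and 0.64. Ighm and Gzma of the lymphocyte list were at −0.73 and −0.65, and Retnlg and Mmp9 of the neutrophil list −1.93 and −0.90. Hbb-bs and Hba-a1 of red blood cells were at −0.95 and −0.96, with multi-mapping reads of the haemoglobin genes left out.

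By Xist and the Y-linked genes all mice were female, so genes more highly expressed in male than in female liver were measured here in female liver. Of 14 such genes 3 fell, 1 rose and 10 were not called, with a median of −0.71 (5 fell and 1 rose adjusted over the list alone). Camera gave adjusted p = 0.0372 with an estimated correlation. The 3 that fell were Slco1a1, the sulfotransferase gene Sult5a1 (from 6.89 ± 1.19 to 1.66 ± 0.77 CPM) and the major urinary protein gene Mup3 (from 1386 ± 246 to 718 ± 154 CPM, a family with near-identical copies), whereas Selenbp2 rose 3.25-fold. The median was −0.70 among the animals with 4-digit numbers and −0.38 among those numbered 98 to 100, and −0.41 with a stricter low-count filter. Of 20 genes more highly expressed in female liver, 1 rose and 0 fell (1 rose and 1 fell adjusted over the list alone). The 1 that rose was Prom1, also on the bile duct list (log2 fold change 2.14, and 1.33 among the animals with 4-digit numbers). Camera did not call the list (adjusted p = 0.639). The list's median was 0.113. Leaving out single libraries gave medians from −0.115 to 0.334, with 0 or 1 higher and 0 to 2 lower.

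Of 24 interferon response genes, 5 fell and 19 were not called, with a median of −0.56 (11 fell adjusted over the list alone). Usp18, a negative regulator of interferon signalling, fell 2.34-fold, from 18.01 ± 2.187 to 7.69 ± 1.93 CPM, and the antiviral gene Rsad2 fell 2.02-fold, from 15.1 ± 2.81 to 7.49 ± 0.737 CPM (SD, n = 4 each, edgeR adjusted p = 0.00135 and 0.00222). Irf7, a transcription factor of the response, and Ifit3 fell 1.56-fold and 1.99-fold. Of 25 genes of cholesterol synthesis and uptake, 6 fell and 19 were not called, with a median of −0.53 (9 fell adjusted over the list alone). Nsdhl, a sterol dehydrogenase gene, fell 2.38-fold, from 15.9 ± 3.06 to 6.69 ± 1.99 CPM. Tm7sf2, a sterol reductase gene, fell 1.62-fold, Hsd17b7 1.44-fold and Hmgcs1, a synthase gene early in the pathway, 1.55-fold. Of 22 genes of fatty acid and triglyceride synthesis 1 fell, Acss2, by 1.41-fold (7 fell adjusted over the list alone, median −0.38). Camera called these lists only at its preset correlation (interferon adjusted p = 0.081, cholesterol adjusted p = 0.233 and fatty acid synthesis adjusted p = 0.0804 with an estimated correlation). Their medians were −0.71, −0.55 and −0.35 among the animals with 4-digit numbers and −0.34, −0.58 and −0.14 among those numbered 98 to 100. The interferon count was 2 without WT replicate 2, 3 without KO replicate 1, 2 or 4 and 8 without WT replicate 3, and the cholesterol count was 3 without WT replicate 2 or KO replicate 3. The cholesterol median was −0.33 without WT replicate 3. The fatty acid synthesis count was 0 without WT replicate 2 or KO replicate 4, 2 without WT replicate 1 and 6 without WT replicate 3. DESeq2 called 6 of that list lower and limma-voom 5.

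Among plasma proteins, Hrg, which encodes histidine-rich glycoprotein, fell from 1204 ± 50.3 to 791 ± 14.2 CPM and was the 1 of 30 members called (2 fell adjusted over the list alone). Camera gave that list adjusted p = 0.0478 at the preset correlation and 0.691 with an estimated one. Its call was lost in 8 of 18 camera and fry alternatives. Of 21 acute phase genes Hpx fell and Itih3 rose 1.48-fold (2 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.164). In that list 3 fell and 2 rose without WT replicate 3. Itih3 was not called without WT replicate 1, 2 or 4 or KO replicate 1, 3 or 4. Of 22 genes of bile acid synthesis and transport, the efflux transporter gene Abcc3 rose 1.46-fold, Amacr rose 1.41-fold and Slco1a1 fell (3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.22). In that list 4 rose and 3 fell without WT replicate 3, 3 rose without WT replicate 4, 2 fell without KO replicate 2, 0 rose without WT replicate 2, and 1 rose without WT replicate 1 or KO replicate 1, 3 or 4. Of 22 genes of lipoprotein assembly and lipid export 2 fell, among them Apoa5, which regulates the clearance of plasma triglycerides, by 1.51-fold (3 fell and 1 rose adjusted over the list alone; 0 fell without KO replicate 3 and 1 without WT replicate 1 or 2 or KO replicate 1 or 4; camera adjusted p = 0.164). Lpl rose 1.86-fold as the 1 called of 19 lipid droplet and uptake genes (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.639). The carnitine carrier gene Slc25a20 fell 1.40-fold as the 1 called of 30 genes of fatty acid oxidation (1 fell adjusted over the list alone; camera adjusted p = 0.731). Ugt1a1, the bilirubin-conjugating enzyme, fell 1.37-fold as the 1 called of 30 cytochrome P450 and conjugation genes (1 fell adjusted over the list alone, camera adjusted p = 0.056). In that list 5 fell and 1 rose without WT replicate 3 and 3 fell without KO replicate 2, but the lowest leave-one-out count was 0. The camera and fry alternatives called the list in 6 of 18 cases, with adjusted p from 0.00234 to 0.711. Foxa3 rose with a log2 fold change of 0.58 as the 1 called of 20 hepatocyte transcription factors (1 rose adjusted over the list alone; camera adjusted p = 0.652).

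**Figure D3:**
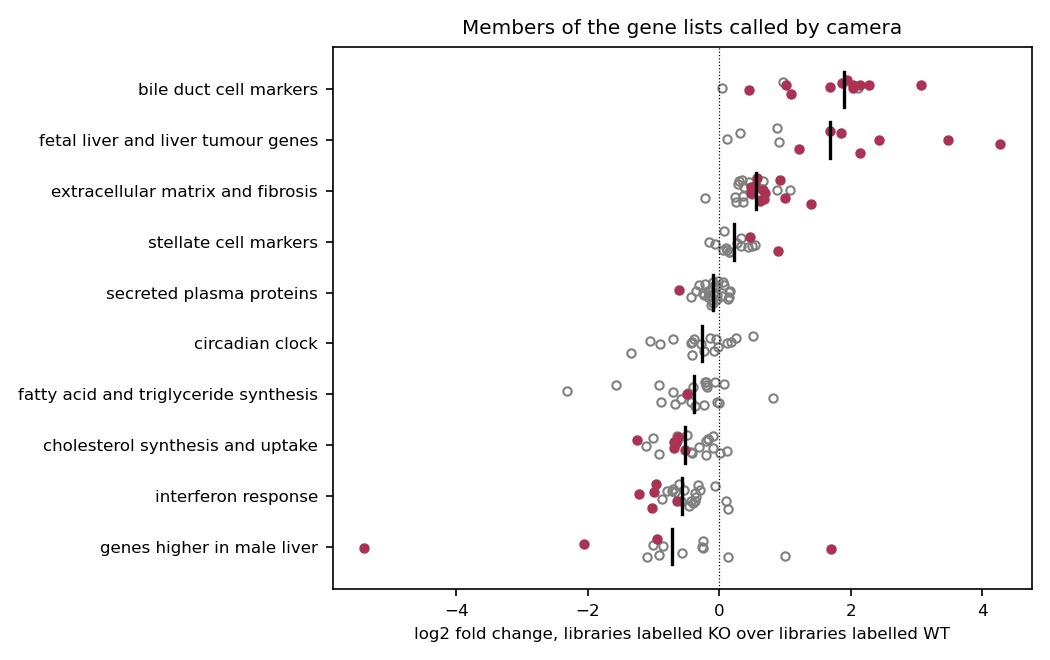
Log2 fold change (horizontal axis, libraries labelled KO over libraries labelled WT) of each measured member of the 10 lists called by camera at the preset correlation. Filled red points are genes called by edgeR, open points are not called, and black lines are medians, from 1.90 for bile duct markers to −0.71 for genes higher in male liver.

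None of 22 measured mRNAs reported in the literature as bound by HuR was called by edgeR over the 8 libraries, across all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 4, DESeq2 called 1 and limma-voom 2. Among the edgeR alternatives 1 rose and 1 fell with the number series as a covariate, 1 rose without WT replicate 3, 1 rose among the animals with 4-digit numbers, and 1 fell without a low-count filter. The list's median log2 fold change was −0.06, its mean 0.00 and its camera direction down (adjusted p = 0.312), so that median and test differ in sign from the mean. Fry's mixed test, which asks whether members changed in either direction, gave adjusted p = 0.0241, and fry's test of one direction adjusted p = 0.109. The mixed test called 18 of the 33 lists, so it does not single out this one. Apob, the structural protein of very low density lipoprotein, was at 9878 ± 777 CPM in the libraries labelled WT and 7520 ± 177 CPM in those labelled KO (log2 fold change −0.39, SE 0.11, edgeR adjusted p = 0.0613). It was called in 4 of 17 alternatives, DESeq2 and limma-voom among them, with adjusted p from 0.000374 to 0.285. Mat2a was at −0.28. Of 12 other proteins that bind AU-rich elements none was called by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05. Ybx1 was at −0.18 and Celf1 at 0.14, and camera gave adjusted p = 0.849.

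In all, 16 lists held no member called by edgeR, with 282 memberships, of which 41 had an unadjusted p under 0.05, DESeq2 called 11, limma-voom called 18 and 7 passed when adjusted over the list alone. The 7 were 2 of amino acid and urea metabolism, 2 of p53 targets and 3 of inflammatory genes. Without WT replicate 3, edgeR called 7 of 23 genes of amino acid and urea metabolism, 6 of them lower. It then also called 2 lower genes of glucose metabolism and 2 of the circadian clock, 1 higher and 1 lower of the cell cycle, 1 higher each of macrophage markers, p53 targets and mRNAs bound by HuR, and 1 lower each of NRF2 targets, lymphocyte markers and inflammatory genes. The circadian clock list had a median of −0.26 and was called by camera only at the preset correlation (adjusted p = 0.234 with an estimated correlation), with Hlf at −0.24. Camera did not call oxidative phosphorylation (adjusted p = 0.132, with Ndufb8 at −0.29 and Cox5b at −0.31), NRF2 targets (0.216, with Gclc at −0.37 and Hmox1 at −1.38), glucose metabolism (0.244, with Irs1 at −0.24), amino acid and urea metabolism (0.832, with Gls2 at 0.41 and Glul at 0.68) or the cell cycle (0.241, with Rrm2 at −0.80 and Tyms at −0.48). Nor did it call p53 targets (0.832, with Aen at −0.46 and Gdf15 at 1.47), the unfolded protein and integrated stress response (0.921, with Atf3 at 0.67 and Atf4 at −0.19) or inflammatory cytokines and NF-kB targets (0.443, with Ccl5 at −1.53 and Socs3 at 1.07). Its adjusted p was 0.216 for endothelial, 0.217 for macrophage, 0.241 for lymphocyte, 0.216 for neutrophil and 0.132 for red blood cell markers. Of the 57 named genes that were called, 39 were called whichever library was left out. The other 18 included Abcc3, Acss2, Amacr, Apoa5, Cenpq, Dnase1l2, Exd1, Foxa3, Hgf, Hmgcs1, Ifit3, Irf7, Itih3, Prom1, Slc25a20, Slc39a5 and Ugt1a1, and their adjusted p reached 0.138 at most in such fits.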

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

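The tests of exchanged or wrong labels, exon content, other liver cell types and number series in this part were chosen after the results had been seen, and the test of smooth muscle genes against the bile duct rise before its own result had been seen.

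Of 188 groups of 4 libraries examined, 9 held a library far from the other 3, where chance gives about 1 in 20 groups, or 9.4. The gap took up 0.887 of the range for Lamc3 (KO 2 at 28.2 CPM, the others from 33.6 to 34.4), 0.873 for Zpr1 (KO 2 at 47.2 CPM), 0.834 for Foxa3 (KO 4 at 67.9 CPM) and 0.856 for Hmox1 (KO 1 at 45.4 CPM, the others from 26.0 to 28.2). In the libraries labelled WT it took up 0.972 for Apob (WT 3 at 11000 CPM, the others from 9460 to 9500), 0.876 for Mat2a (WT 2 at 135 CPM), 0.869 for Nsdhl (WT 4 at 11.4 CPM), 0.912 for Cox5b (WT 4 at 65.8 CPM) and 0.879 for Ifit3 (WT 3 highest, the others from 10.9 to 11.2 CPM).

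Elavl1 was not lower in the libraries labelled KO. An exchange of a library between the groups is argued against, since it needs a library out of place in each group, 0 libraries lay on the other group's side of the first principal component, and over the genes called without it each library labelled KO lay at most 0.271 of the way to the libraries labelled WT. WT replicate 3 lay 0.545 of the way to the libraries labelled KO over the 1228 genes called without it. This leaves a wrong label of that library alone open. Its bile duct score, however, was 1.70 (mean log2 CPM). That was nearer the 1.38 to 1.41 of the other WT libraries than the 2.73 to 3.32 of the KO libraries. Without WT replicate 3 Elavl1 was still higher, at a log2 fold change of 0.27. An effect of number series also stays open, since WT replicate 3 shares its series with KO replicates 3 and 4. After removal of group means it correlated with them at 0.122 and 0.222, and with KO replicates 1 and 2 at −0.123 and −0.2. The negative values largely follow from the positive ones through that removal and are not a separate observation. As the only WT library of its series, WT replicate 3 cannot separate the series from a wrong label. An exchange of the labels of whole groups cannot be told apart from the labels as given, because the ratio of Elavl1 in WT over KO was 0.838, neither at or above 1 nor at or below 0.5. A deletion that leaves most of the transcript in place may also give this value, as the second longest exon block of Elavl1 holds 3.75% of its exonic length, counts per exon were not analysed here, and a loss of HuR protein without a loss of its mRNA was not tested.

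Bile duct, matrix and fetal genes were higher in the libraries labelled KO. A lower share of hepatocytes that raised all other cell types alike is argued against for the bile duct and fetal genes. Their lists rose by 1.48 and 1.54 more than the endothelial list on the log2 scale (SE 0.169 and 0.222, exact permutation p = 0.0286 each). The matrix list rose by 0.47 more (SE 0.0752, exact permutation p = 0.0286). That lies beyond 2 SE, the rule set for the matrix and fetal lists, but short of the excess of 0.5 asked of the bile duct list. For the matrix genes this cause is argued against only by the looser rule. More large ducts, vessel wall or neighbouring tissue in the sampled piece stays open. The mean log2 level of 8 smooth muscle genes was 0.357 higher (SE 0.123, exact permutation p = 0.0571). That was below 0.783 and 0.81, the values at 50% of the bile duct and fetal rises, but not below 0.277, the value for the matrix genes. It argues only against added tissue that raises smooth muscle genes at least 50% as far as the bile duct or fetal genes. The 50% was an assumption, and smooth muscle genes cannot show added tissue that holds little smooth muscle. The number series does not account for the whole difference, since the bile duct, matrix and fetal medians were 1.34, 0.424 and 1.07 among the animals with 4-digit numbers. An expansion of bile duct cells or their genes being switched on in hepatocytes, with the HuR genotype as the cause, may explain the bile duct and fetal genes, and these data cannot separate such sources.

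Of 24 interferon genes 5 were lower in the libraries labelled KO, and camera called the list only at its preset correlation (adjusted p = 0.081 with an estimated correlation). Fewer macrophages are argued against only for a loss that lowers macrophage genes at least 50% as far as the interferon genes. The macrophage list was 0.231 higher (SE 0.131, exact permutation p = 0.143). Among the animals with 4-digit numbers its median was −0.07 and its mean level differed by 0.0547 (SE 0.162). That lay above −0.361, the value expected at 50% of the interferon fall there, by 0.416 (SE 0.162). That series holds 3 libraries labelled WT and 2 labelled KO, so its SE is itself uncertain, and the 50% was an assumption. Fewer lymphocytes stay open, as their list was at −0.231 with an SE of 0.245 (exact permutation p = 0.429), which does not separate it from 50% of the interferon fall, and among the animals with 4-digit numbers its median was −0.26 (camera adjusted p = 0.00153 at the preset correlation). The number series does not account for the whole fall, with a median of −0.714 among the animals with 4-digit numbers and −0.34 among those numbered 98 to 100. Lower interferon signalling tied to genotype stays among the open explanations, and housing or infection history was not given in the sources used here.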

How the results depend on the processing

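The comparison within the animals with 4-digit numbers was chosen after the data had been seen, and the other alternatives before. Elavl1 stayed higher and uncalled in the alternatives run for it, which leave out glmTreat, with log2 fold changes from 0.15 without WT replicate 1 to 0.34 within the animals with 4-digit numbers and adjusted p from 0.193 to 0.57. Against 340 genes higher and 201 lower, DESeq2 called 564 and 437, limma-voom with quality weights 582 and 453, and glmTreat against a fold of 1.5, a stricter question, 53 and 11. Without a low-count filter 328 were lower, from 24462 genes tested, and with the number series as a covariate 308 were lower. Within the animals with 4-digit numbers, with fewer libraries, 215 were higher. Leaving out single libraries gave 151 to 710 higher and 71 to 534 lower. The counts were 209 and 108 without WT replicate 1, 151 and 71 without WT replicate 2, 710 and 534 without WT replicate 3, 218 and 113 without KO replicate 1, 158 and 73 without KO replicate 3, and 170 and 83 without KO replicate 4. On the first principal component WT replicate 3 lies nearest the KO libraries among the WT libraries, and without it 528 of the 541 called genes stayed called. Why the tools differ in number was not tested. No called gene changed direction in any alternative. With the replicate number as a block 353 were higher and 211 lower, 436 of them shared with the 541, and 10 cholesterol genes were lower instead of 6. Same-numbered libraries correlated at 0.03, 0.03, 0.12 and −0.15 after removal of group means, so the replicate numbers do not pair the mice. Every pair of a WT and a KO library within a number series correlated positively, at 0.0179 to 0.222. Every such pair across the series correlated negatively, at −0.0139 to −0.2. Removing the group means ties the deviations within a group together, so these signs are not independent observations. They also rest on WT replicate 3, the only WT library of its series, and cannot separate the series from that library. A structure shared by number series, which the main comparison does not model, thus stays open. Upper quartile scaling gave 394 higher and 164 lower. Camera called 10 lists at the preset correlation, 4 with an estimated correlation and 9 to 13 under the other alternatives, fry called 7 and its mixed test 18. The sex covariate was not run, since all libraries came from 1 sex. In the simulated test 3 of 21 changes of 1.5-fold were found among genes below the median level and 21 of 29 among the others, so low counts limit what can be called.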

Other observations

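The groups of genes in the paragraph below and the tests of genes near Elavl1 and of the share of motif-rich genes that fell were chosen after the values had been seen, the count of splits with an estimated correlation after that at the preset correlation had been seen, and the other tests before.

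Of 27 genes of the basement membrane and its epithelial receptors, among them laminins, type IV collagens and integrins, 14 were higher in the libraries labelled KO, 0 were lower and 13 were not called. Itgb8 rose from 1.89 ± 1.02 to 6.52 ± 1.85 CPM (SD, n = 4 each). Of 22 genes of the cilium, an organelle that bile duct cells carry and hepatocytes lack, 11 were higher and 0 lower, among them Pkhd1 (9.05 ± 1.51 to 25.3 ± 3.18 CPM), Bicc1 (7.98 ± 3.21 to 26.8 ± 4.94 CPM) and Glis3 (1.76 ± 0.735 to 5.89 ± 1.77 CPM), whereas Pkd1 was at 52.3 and 52.9 CPM and not called. Of 12 measured imprinted growth genes 4 were higher, H19, Igf2, Peg3 (23.7 ± 3.51 to 56.9 ± 13.8 CPM) and Grb10 (7.39 ± 0.662 to 14.6 ± 2.30 CPM). Of 20 targets of the transcriptional regulator YAP 5 were higher, Ankrd1, Ajuba, Ptpn14, Arhgef17 and Amotl1, while Ccn1 and Ccn2 were not called. Of 14 genes of antigen presentation by MHC class I 5 were lower, H2-K1 (1154 ± 254 to 622 ± 31.3 CPM), H2-D1, H2-Q10, B2m (1332 ± 145 to 957 ± 85.5 CPM) and Cd1d1. Of 19 transcripts of the mitochondrial chromosome 2 were higher, mt-Rnr2 (3923 ± 973 to 6608 ± 503 CPM) and mt-Nd6 (30.7 ± 6.36 to 56.8 ± 10.8 CPM), and 18 had positive fold changes. Some of the 18 rest on few reads, such as mt-Nd3 at 0.810 and 1.22 CPM and mt-Nd4l at 0.553 and 0.797 CPM. Because these groups were assembled around called genes, and Ccn2, Col4a1, Col4a2, H19, Igf2, Psmb8, Psmb9 and Tap1 also stand on lists fixed earlier, their tests do not show that the pattern holds elsewhere. Camera with an estimated correlation gave adjusted p = 0.00511 for basement membrane, 0.0173 for cilium, 0.016 for imprinted genes, 0.0205 for YAP targets, 0.0719 for MHC class I and 0.0724 for mitochondrial transcripts.

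At the adjusted threshold the 541 called genes exceed what other splits of the libraries gave. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many, the real split. With only 35 splits this makes chance unlikely for the count at that threshold but cannot exclude it. The highest other split gave 186. At an unadjusted p under 0.05, however, that split gave 2783 genes and the real split 2643, so there the real split did not lead. That other split exchanges WT replicate 3 and KO replicate 2, which puts all animals numbered 98 to 100 on the same side, and among the animals with 4-digit numbers alone 215 genes were higher and 159 lower. For the 10 lists called at the preset correlation chance cannot be excluded, since 23 of the 35 splits called as many and the highest other called 16. With an estimated correlation 4 lists were called, 1 of 35 splits gave as many, the real split, and the highest other called 1. Chance is thus unlikely for that count but, with only 35 splits, not excluded.

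If HuR stabilised mRNAs through U-rich sites, genes rich in them might be lower in the libraries labelled KO. In 12407 genes with an annotated 3′ UTR of at least 100 nt, the genes with the most sites per kb (the densest 3103, with at least 3.8 sites per kb of 3 U, then A, G or U, then 3 U) had a median log2 fold change of −0.01, against 0.00 in length-matched genes, and camera gave p = 0.765 with an estimated correlation. Among them 85 genes rose and 57 fell, or 1.84%. Of the 3103 length-matched genes 71 rose and 40 fell, or 1.29% (odds ratio of a fall 1.43, 95% interval 0.937 to 2.21, two-sided Fisher's exact p = 0.101). Of all 9304 other genes searched 239 rose and 108 fell (odds ratio 1.59, 95% interval 1.13 to 2.22, two-sided Fisher's exact p = 0.0064). The camera test, set beforehand to decide, compares the list as a whole and cannot show a fall of a minority, so a fall of some such mRNAs stays open. A chromosome segment of another strain around the Elavl1 allele could also alter neighbouring genes. Within 10 Mb of Elavl1 4 of 72 genes were called (5.56%, against 3.68% elsewhere, odds ratio 1.54, 95% interval 0.406 to 4.14, two-sided Fisher's exact p = 0.341), Slc10a2, Col4a1, Col4a2 and Gas6, too few to settle it.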
